A study of Mus musculus with 2 samples.

How the data were processed

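ChIP-seq reads obtained with an antibody against Tnni2 were deposited for 1 mutant and 1 wild-type library of primary osteoblasts of 129sv mice. Reads were aligned with Bowtie, per the submitters' processing notes. The version, the mismatch settings and any filter on repeated or multiply placed reads are not given in the sources used here. Each deposited file lists 1 aligned read per line with its start and end, its strand and a score. The score deposited by the authors is 255 on every line of both files and was not used. Every read spans 36 bp and every read name is distinct. The files hold neither counts nor peaks, so all counts given here were made from read positions.

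The series text names mouse reference 8. The last reads on chromosome 7 end at 152524453, beyond the last gene on chromosome 7 in the GRCm38 gene table at hand. The last gene does not mark the end of a chromosome, so this alone does not settle the build. From general knowledge of mouse builds, this position lies beyond the end of chromosome 7 in GRCm38 and in mm8, and within that of mm9. Coordinates are therefore printed as the files give them, counted from 1, with the build uncertain. No annotation of that build was used. Comparisons of promoters and of gene lists had been set down before the data were examined, on the condition that such an annotation was at hand, and were not run. Regions are thus given without gene names, exons or introns.

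Reads were reduced to distinct positions (chromosome, 5′ end and strand), since fragments copied by PCR are not independent molecules. Libraries were scaled to their distinct positions on chromosomes 1 to 19, 2927228 in the mutant and 2821498 in the wild-type library. A ratio is always mutant over wild type after this scaling, with an exact Clopper-Pearson 95% interval of the split of counts between the libraries. Such intervals compare these 2 libraries, not the genotypes. Fragment length was taken as the distance of 100 to 400 bp at which opposite-strand pairs were most frequent on the autosomes, after smoothing over 11 bp.

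Enriched regions were called in 500 bp bins on chromosomes 1 to 19 and X, with reads shifted by 50% of the fragment length. A Poisson test compared each bin with the larger of the library's mean bin and the mean of the 10 kb around it without the bin. Bins with a Benjamini-Hochberg q under 0.01 over 5277834 bins were kept, and adjacent ones merged. The mean bin held 0.568 positions in the mutant and 0.553 in the wild-type library. Regions of both libraries were merged to 130 and compared with intervals widened by Bonferroni correction. A region differed where this interval excluded 1 and the ratio was at least 2-fold in either direction. Bins of 100 kb with 100 or more positions in the libraries together were compared with the same interval. The log2 ratios of bins used 0.5 added to each count. By a rule set before the data were examined, the text names the 10 regions with the highest fold over background among those with 20 or more positions in each library, the regions that differ and all chromosomes. Runs of 100 kb bins outside the interval were formed after the data were seen, with X measured against its own ratio, and all of these are named.

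The calling was tested on simulated data drawn from the densities of each real library, with 200 bins raised 5-, 10-, 20- or 40-fold, 50 of each. Of the 40-fold bins 100.0% were found in both libraries, and of the 5-fold bins 6.0% in the mutant and 0.0% in the wild-type library. Calls at unchanged bins numbered 1 and 3. The comparison between libraries, on counts of the 130 regions drawn with no difference, gave 0 calls in 2600. Both simulations drew independent counts from the model that the test itself assumes, at rates flat over 100 kb for the calling. Few false calls were therefore to be foreseen. Real reads are clustered, so false calls among the real regions may be more frequent and were not measured. Alternatives covered repeated reads, bin size, read shift, background, threshold, depth, overlap and scaling. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.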

Results

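Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which reads the DNA fragments recovered with an antibody, was performed in primary mouse osteoblasts, the bone-forming cells, with an antibody against Tnni2. Tnni2 encodes the troponin I of fast skeletal muscle, the inhibitory subunit of the troponin complex. One library came from animals homozygous for the del175k allele of Tnni2 (mutant) and 1 from wild-type littermates. The series text gives n = 3 for the animals, and no label says how they were combined. Each comparison below is therefore between 2 libraries, has no replicate check and carries no p-value for the genotype. No input or control-antibody library was analysed here. The mutant library held 3273273 aligned reads at 3003795 distinct positions (chromosome, 5′ end and strand), and the wild-type library held 3305140 reads at 2920353 distinct positions. Reads beyond the first at a position made up 8.23% of the mutant library (95% exact binomial interval 8.20 to 8.26%) and 11.6% of the wild-type library (11.6 to 11.7%). Intervals given here cover counting error only.

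The sex chromosomes differed far more between the libraries than any autosome did. Chromosome X held 72417 distinct positions in the mutant library and 97519 in the wild-type library, a depth-scaled mutant to wild-type ratio of 0.716 (95% exact interval 0.709 to 0.723). Chromosome Y held 4036 and 1216, a ratio of 3.20 (3.00 to 3.41). The direction held along X and along the stretch of Y that held reads, where 5′ ends reached only position 2902520. On X, 149 of 151 bins of 1000 kb lay below a ratio of 1, with a median of 0.722, and on Y all 21 bins of 100 kb with 20 or more positions lay above 1. The 19 autosomes lay between 0.967 on chromosome 11 (0.961 to 0.974) and 1.04 on chromosome 3 (1.03 to 1.04). Counting error excluded a ratio of 1 for 14 autosomes, 7 above and 7 below it. The mitochondrial genome held 114 positions in the mutant library and 120 in the wild-type library, and its ratio of 0.916 was not distinguishable from 1 at this depth (0.702 to 1.19).

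**Figure D1:**
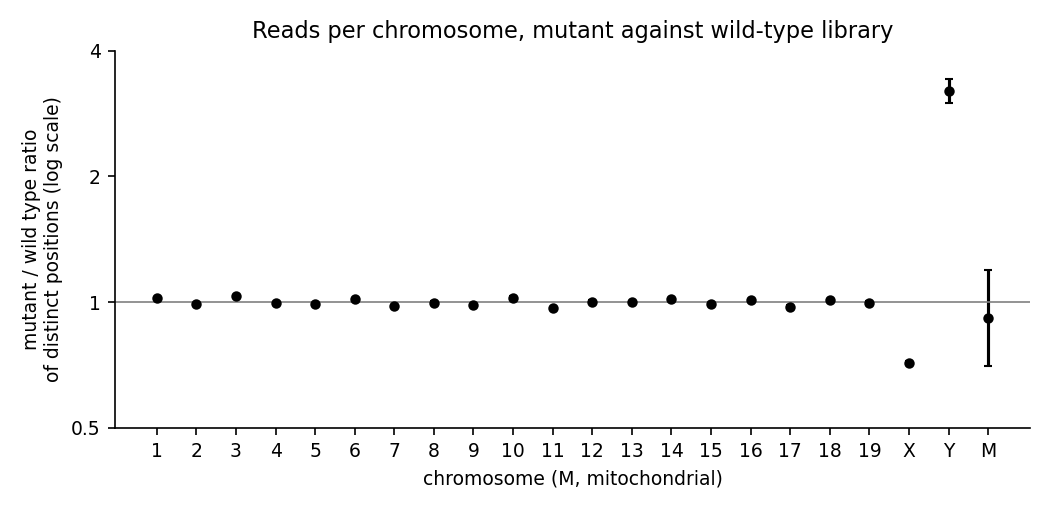
Mutant to wild-type ratio of distinct positions per chromosome, scaled to the distinct positions on chromosomes 1 to 19, on a log axis. Points are 1 library against 1 library and bars are 95% exact intervals, hidden by the points for most autosomes. X lies at 0.716 and Y at 3.20, while the autosomes lie between 0.967 and 1.04.

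Local excesses of reads, termed enriched regions, were called in each library against its own surroundings. Without an input library they cannot be credited to the antibody rather than to repeated sequence or mappability. For example, the region on chromosome 2 from 98506501 to 98507500 held 3154 reads at 424 positions in the mutant library. In the wild-type library it held 3042 reads at 419 positions. The mutant library gave 88 enriched regions and the wild-type library 92, and they held few of the reads. They took 0.126% of the distinct positions on chromosomes 1 to 19 and X in the mutant library (0.122 to 0.130%) and 0.134% in the wild-type library (0.129 to 0.138%). The median region held 17.5 positions at 14.1 times its background in the mutant library and 15 positions at 14.5 times its background in the wild-type library. The reads within regions were concentrated. The 10 fullest regions held 52.9% of the region positions in the mutant library and 57.5% in the wild-type library. Chromosome 9 carried most regions in both, 14 in the mutant library and 12 in the wild-type library. In the mutant library 16 regions on 6 chromosomes, and in the wild-type library 15 on 7 chromosomes, started before 3.5 Mb, next to the unassembled centromeric end of the mouse chromosomes. These held 26.7% and 22.9% of the region positions. With every aligned read counted, the calls rose to 339 and 924 regions. At this depth a simulated bin enriched 10-fold was found in 26.0% of cases in the mutant library and 32.0% in the wild-type library, and one enriched 20-fold in 88.0% and 82.0%.

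Of the 10 most enriched regions of each library, 7 were the same places, and the intervals of their ratios between the libraries all included 1. By distinct positions the highest fold over background lay on chromosome 4 from 70039001 to 70039500, in the coordinates of the deposited reads. It held 89 positions in the mutant library, 127 times its background (95% Poisson interval 102 to 156), and 90 in the wild-type library, 94.7 times its background (76.2 to 116). Its depth-scaled ratio was 0.953 (0.703 to 1.29). The region on chromosome X from 139917501 to 139918000 held 33 positions in each library, 58.1 and 59.7 times background, with a ratio of 0.964 (0.577 to 1.61). With every aligned read counted this order turns, with 226 and 157 times background for the region on X and 216 and 150 times for that on chromosome 4. The region on chromosome 12 from 75905001 to 75905500 held 39 and 30 positions, with a ratio of 1.25 (0.759 to 2.09). Those on chromosome 6 from 103599001 to 103599500 and on chromosome 18 from 40467501 to 40468000 had ratios of 0.816 (0.441 to 1.5) and 1.09 (0.598 to 2.0). The regions on chromosome 15 from 74917001 to 74917500 and on chromosome 12 from 3109501 to 3110500 had ratios of 1.10 (0.736 to 1.66) and 0.869 (0.592 to 1.27). The mutant list also held chromosome X from 73844001, chromosome 16 from 10975001 and chromosome 9 from 35112501. Their ratios were 1.27 (0.671 to 2.44), 1.48 (0.702 to 3.24) and 1.03 (0.863 to 1.23). The first, at 27.8 times background, missed the wild-type list by its 19 positions there, 29.2 times background, where 20 were required. The wild-type list also held chromosome 5 from 147072501 and from 114623001 and chromosome 11 from 108873001. Their ratios were 0.335 (0.130 to 0.776), 0.627 (0.286 to 1.32) and 0.460 (0.260 to 0.790). The intervals of the first and last of these exclude 1 for a single region but not after allowance for all regions compared. Of these 13 places, the one on chromosome 5 from 147072501 was not called in the other library.

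Of the mutant regions 49 of 88 (55.7%, exact interval 44.7 to 66.3%) overlapped a wild-type region, and of the wild-type regions 48 of 92 (52.2%, 41.5 to 62.7%) overlapped a mutant region. With every aligned read counted these shares were 18.0% and 6.39%. In 100 random placements on the same chromosomes the overlap was at most 0 and 1 regions. Places where reads pile up for reasons other than the antibody would also be shared, so the overlap does not show antibody binding. Regions called in 1 library alone mostly held few positions, and summed over regions they lay above background in the other library. The 39 called in the mutant library alone had a median of 10 positions and at most 56. Their summed wild-type positions were 2.72 times background (2.38 to 3.10), with 5 regions at 0. The 44 called in the wild-type library alone had a median of 11 positions and at most 51. Their summed mutant positions were 3.72 times background (3.26 to 4.23), with 6 regions at 0. Because these regions were chosen for a high count in 1 library, their level there is overstated. Regions were therefore also called in a random subset of 1460176 positions and measured in positions not used for the call. The 44 regions called in a mutant subset lay at 6.35 times background in an equal subset of the remaining mutant positions (6.0 to 6.71). In an equal wild-type subset they lay at 6.21 times background (5.88 to 6.57). The 44 called in a wild-type subset lay at 6.0 times background in the remaining wild-type positions (5.68 to 6.34) and at 6.38 times in an equal mutant subset (6.03 to 6.75). For the mutant calls each summed value lay within the interval of the other. For the wild-type calls each lay outside the interval of the other, with the higher value in the mutant subset. The median region was higher in the library of the call in both cases, at 12.5 times background against 8.03 for the mutant calls and 15.6 against 12.3 for the wild-type calls. The differences between these medians were not tested. Subsets of 1 library may not be independent. If both ends of copied fragments were read, which is left open below, they could fall into different subsets and favour the library of the call.

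Among the 130 regions called in either library, 3 differed by 2-fold or more with an interval, widened for 130 regions, that excluded 1, 2 of them higher and 1 lower in the mutant library. With every aligned read counted, 6 of the 130 differed, 2 higher and 4 lower. The region on chromosome 5 from 105356501 to 105357500 held 47 positions in the mutant library and 10 in the wild-type library, a ratio of 4.53 (95% interval 2.26 to 10.1). The region on chromosome X from 121307001 to 121309000 held 145 and 51, a ratio of 2.74 (1.98 to 3.85), against 0.716 for the whole of X. It lies inside 200 kb of X, from 121200001 to 121400000, with a ratio of 2.30 (1.88 to 2.82). The sparsely covered 1000 kb on either side of that stretch also had a ratio of 2.30. The region on chromosome X from 166407501 to 166408000 held 0 and 14, a ratio with an upper 95% limit of 0.291, or 0.812 when widened for all regions. The widened interval includes the 0.716 of the whole of X. Measured against X's own level, this region would therefore not have been called lower. A further region, on chromosome 17 from 39980001 to 39983500, held the most positions of any. Its 489 mutant and 748 wild-type positions gave a ratio of 0.630 (0.561 to 0.707), below the 2-fold rule. It was named after its values were seen. Of all 130 regions, 50 lay within 1.5-fold of each other, and for 43 the unwidened 95% interval excluded 1, against 6.5 by chance for regions not chosen on their counts. Of the 35 regions with 50 or more positions in the libraries together, 30 lay within 1.5-fold, with a median ratio of 1.03. A region absent from 1 library needed 13 positions in the other to be called. With 500 bp bins of 20 or more positions in place of called regions, 1 of 268 bins differed. In simulated data at these region counts, 4-fold differences were found in 34.6% of cases and 8-fold differences in 50.5%.

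**Figure D2:**
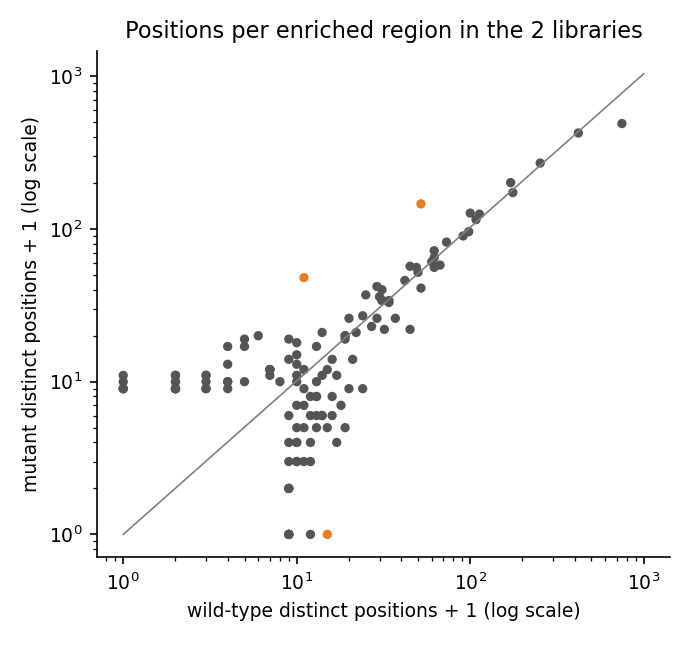
Distinct positions plus 1 in each of the 130 regions called in either library, wild type on the x axis and mutant on the y axis, both on log scales. The line marks equal depth-scaled levels and orange points are the 3 regions that differed. Of the 35 regions with 50 or more positions in the libraries together, 30 lie within 1.5-fold of the line. The fullest region, on chromosome 17 from 39980001, lies below it, with 489 mutant and 748 wild-type positions. The orange points on chromosome 5 (47 and 10) and on X from 121307001 (145 and 51) are also well filled. The other regions far from the line are mostly sparse ones near the calling limit.

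Over the genome, 45 of 23586 bins of 100 kb had a ratio outside the interval that counting error allows for that many bins. Of these, 28 lay on X and 17 on autosomes, 6 of them higher and 11 lower in the mutant library. Measured against X's own ratio, 4 bins on X lay outside. Autosomal log2 ratios had an SD of 0.24 over bins, against 0.19 from binomial sampling of the same counts. Ratios fell with read density. Across 2392 autosomal bins of 1000 kb, the ratio and the summed positions had a Spearman rho of -0.764 and a Pearson r of -0.724 on the log2 ratio. These are correlations across bins of 2 libraries, and bins are not replicates. The sparsest 479 bins had a summed ratio of 1.12 and the densest 479 a summed ratio of 0.927.

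The autosomal bins outside the interval formed 11 runs, 3 of them of adjacent bins. On chromosome 2 from 77700001 to 77900000 the mutant library held 1395 positions and the wild-type library 413, a ratio of 3.26 (2.92 to 3.64). There the mutant density was 5.55 times that of the 1000 kb on either side, and the wild-type density 1.73 times. On chromosome 17 from 30600001 to 31100000 the libraries held 867 and 1890 positions, a ratio of 0.442 (0.408 to 0.479). The mutant density there was 0.979 times that of its flanks and the wild-type density 2.04 times. On chromosome 17 from 27400001 to 27600000 they held 372 and 671, a ratio of 0.534 (0.470 to 0.607), with densities 1.03 and 1.71 times the flanks. Of the 8 single bins, 4 were higher in the mutant library. These lay on chromosome 3 from 25400001 (ratio 1.85), chromosome 6 from 90400001 (1.57), chromosome 9 from 46800001 (1.59) and chromosome 15 from 6000001 (2.84). The others were lower in the mutant library. They lay on chromosome 4 from 140200001 (0.546), chromosome 7 from 38900001 (0.529), chromosome 8 from 8500001 (0.594) and chromosome 17 from 39900001 (0.660). The bin on chromosome 17 held 650 mutant and 949 wild-type positions. It contains the region from 39980001 to 39983500 described above, which held 489 and 748, so the 2 are not separate observations.

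**Figure D3:**
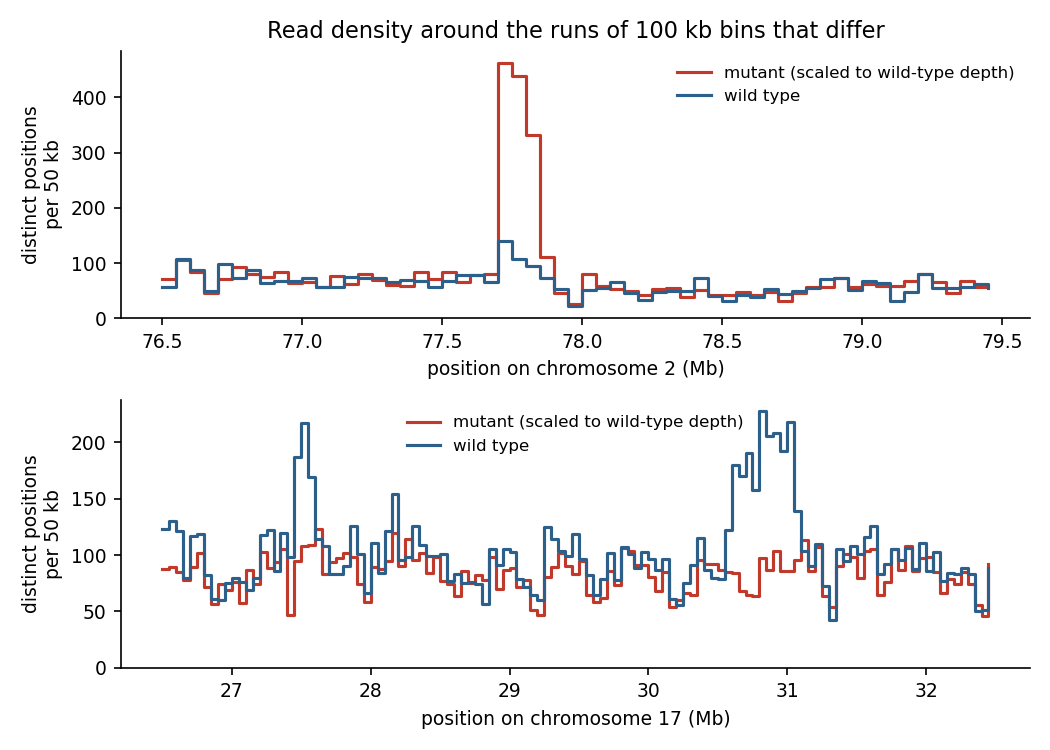
Distinct positions per 50 kb around the runs on chromosomes 2 and 17, with the mutant library scaled to the wild-type depth. The mutant library rises above its flanks on chromosome 2 from 77700001 to 77900000, and the wild-type library rises above its flanks in both runs on chromosome 17.

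Clustering of reads over the autosomes, with and without the called regions, was measured from pairs of reads. Between 100 and 400 bp, reads on opposite strands were most often 216 bp apart in the mutant library and 213 bp apart in the wild-type library. At that distance they were 1.70 and 1.82 times as frequent as at 500 to 600 bp. With the called regions and the 2 kb around them left out, the values were 1.70 and 1.84. At the read length of 36 bp the ratio was then 1.22 in the mutant library and 1.24 in the wild-type library, against 1.83 and 1.82 with all positions. Reads on the same strand were also clustered outside the called regions. Pairs 5 to 30 bp apart were 1.38 times as frequent in the mutant library and 1.41 times in the wild-type library as pairs 500 to 600 bp apart. Pairs 100 to 200 bp apart were 1.16 and 1.18 times as frequent. With 1 library per genotype, the difference between the libraries in these values has no replicate check.

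**Figure D4:**
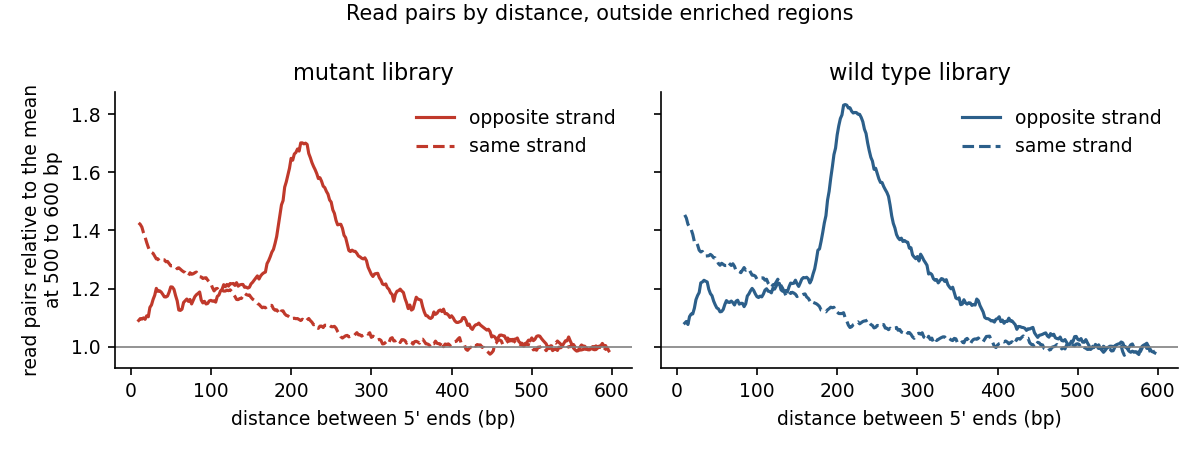
Number of read pairs by the distance between their 5′ ends, relative to the mean at 500 to 600 bp, outside the called regions of the mutant (left) and wild-type (right) library. Solid lines are pairs on opposite strands, which peak near 215 and 213 bp, and dashed lines are pairs on the same strand, which decline with distance.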

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

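Counting every aligned read raised the enriched regions from 88 to 339 in the mutant library and from 92 to 924 in the wild-type library, lowered their overlap to 18.0% of mutant and 6.39% of wild-type regions, and gave 6 regions that differ, 2 higher and 4 lower in the mutant library. A threshold of q under 1e-05 left 48 and 55 regions, of which 75% and 65.5% overlapped. Bins of 200 or 1000 bp, no shift, a 50 kb background and thinning of the deeper library left both counts of regions within 1.5 times. The regions that differ numbered 3 with scaling to the median of 100 kb bins. When 500 bp bins with 20 or more positions were compared, 1 bin differed. It lies on X from 121308501, inside the region from 121307001, and no bin of the region on chromosome 5 differed; the region on X from 166407501, with 14 positions, was not tested. Bins outside the counting interval numbered 17 of 53 at 10 kb, where few bins held enough positions, 195 of 2543 at 1000 kb and, chosen after the data were seen, 21 of 23586 with X scaled to its own ratio. The SD of autosomal log2 ratios was 0.96 at 10 kb, against 0.24 from sampling, and 0.14 at 1000 kb, against 0.07. The ratios of X and Y with every read, also chosen after the data were seen, were 0.718 and 3.33. All 20 named enriched regions were called again under 4 alternatives (all reads, no shift, 50 kb background and the stricter threshold), but 6 of the folds over background rose by over 1.5 times with all reads, 6 with the 50 kb background and 1 with no shift. The 3 regions that differ did so again with every read and with scaling to the median, the alternatives that keep the same regions. With 1 library per genotype, no library could be left out and no paired analysis was possible because the groups hold 1 library each. Other window sizes and all-read counts for promoters and gene lists were not run, as no annotation of the files' build was used. Depth limits the calls: a 10-fold enriched bin was found in 26.0% and 32.0% of simulated cases. The causes of these changes were not tested, except that the 10 kb and 1000 kb settings change the number of bins compared.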

Other observations

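With X measured against its own ratio, a setting chosen after the data were seen, 3 runs of 100 kb bins on X went against the chromosome as a whole. They lay from 53200001 to 53300000, from 120100001 to 120200000 and from 121200001 to 121400000. Together they held 546 distinct positions in the mutant library and 235 in the wild-type library, a ratio of 2.24 (95% exact interval 1.92 to 2.62), where X as a whole had 0.716 and Y had 3.20. The bins were chosen on these same counts for lying off X's ratio, and the interval does not allow for that choice. The 1000 kb on either side had ratios of 0.732 for the run from 53200001 and 0.779 for that from 120100001. For the run from 121200001 the flanks had 2.30, on only 4.65 mutant and 1.95 wild-type positions per 100 kb. The difference there is thus not bounded by the run. The read names add a measurement of the sequencing. Both libraries carry lane 7 and tiles 1 to 120, and they share 0 cluster positions within a tile, while mismatched tiles share 199 to 260 by chance. Within 15 coordinate units of a mutant cluster lay 0 wild-type clusters of the same tile, against 166436 of the next tile.

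Of the tests below, those on male cells, on copy number and on lanes were chosen only after the pattern was seen.

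Chromosome X was lower and Y higher in the mutant library. The trend of ratio on read density through the autosomes predicts 1.11 for X, from which X deviates by -33.4 residual SDs of the autosomes. The autosomes span 2072 to 2790 positions per Mb in the libraries together, and X has 1020. The SDs therefore leave out the error of extending the line that far. The fitted trend predicts a ratio above 1, and X lies below 1, so the trend as fitted does not account for X. The 2 libraries may differ in their share of male cells. Of the 1000 kb bins of X 98.7% lay below 1, so the difference is not confined to a part of X. All 21 tested bins of Y lay above 1. Read 5′ ends on Y reached only position 2902520, so any part of Y beyond it was not measured. X held 0.367 times the autosomal density per Mb in the mutant library and 0.513 times in the wild-type library. Male and female cells alone would give 0.5 to 1, if X and autosomes yielded reads equally per Mb. The mutant value lies below that range, so the level of X gives no share of male cells. An unequal yield shared by the libraries cancels in the ratios of X and Y. These would correspond to 73.2% male cells in the mutant and 22.9% in the wild-type library, if nothing else differed and female cells gave no reads on Y. Autosomal ratios fell with read density, from 1.12 in the sparsest bins to 0.927 in the densest, so the libraries did differ otherwise. Whether female cells gave reads on Y was not tested. The 2 percentages are therefore not estimates of the share of male cells. Loss of sex chromosomes in culture would have to involve both X and Y to change both ratios. It cannot be told apart from different shares of male cells here, since neither the level of X nor the labels, which give no sex, decide.

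The runs of adjacent 100 kb bins on chromosomes 2 and 17 may reflect a copy number difference between the animals behind the libraries. Of their 88 bins of 10 kb with 10 or more positions, 84 (95.5%) lay on the run's side of 1, so the change is not confined to a few of these bins. The runs were chosen from these same positions, and enrichment spread along a run would give a like share. The share therefore does not single out copy number. Narrow enriched sites, called in 500 bp bins, do not account for them, since they held 0.285% of the runs' positions. Enrichment spread over a whole run could not be called, because it raises the 10 kb background as well. The share in called sites therefore says nothing about broad enrichment. Separate sequencing lanes do not account for the runs, given 0 shared cluster positions. Inbred mouse strains are known to differ in copy number on chromosome 17, for example by a duplication that includes Glo1, but whether a run matches it was not tested, as no annotation of the files' build was used. A difference in strain background, between single animals or in broad enrichment stays open.

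Outside the called regions, opposite-strand pairs about 1 fragment apart were in excess, and 2 explanations were compared. If they came from different fragments clustered at sites, same-strand pairs at short distance would show a like excess; if both ends of copied fragments had been read, they would not. The same-strand excess was 62.2% of the opposite-strand excess in the mutant library and 56.9% in the wild-type library, between the bounds of 50% and 90% set beforehand. Neither explanation alone was excluded or met, and the 2 cannot be told apart here, since both may contribute and no input library was analysed. Clustering of distinct fragments may also come from open chromatin, base composition or mappability rather than the antibody, which these files alone do not separate.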
